A study of Homo sapiens with 68 samples.

How the data were processed

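Lymphocytes of CLL patients were isolated by negative selection, kept frozen, and their total RNA was extracted with Qiagen kits, labelled with biotin and hybridised to HG-U133 Plus 2.0 arrays, per the labels' protocols. The deposited value table holds 1 linear signal intensity per probe set and array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. MAS5 combines the perfect match and mismatch probes of a probe set and scales each array by a trimmed mean. The 2% trimmed mean of the deposited intensities was 500 on every array, with a CV of 0.000973%, so no further scaling was applied. MAS5 values of dim probe sets are noisy, which is why a pseudocount of 16 was added before log2 and dim genes were left out. Array run files deposited with the samples gave scan day, project, chip lot, fluidics station and scanner, and were used for batch labels; these fields are text with no intensity or other measured value.

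The table holds 54675 probe sets, of which 62 are controls. Of the other 54613, 41091 have 1 gene symbol in the annotation table, 1801 have several and 11721 have none; the last 2 kinds were not named. Gene numbers of 41037 probe sets matched the current RefSeq gene table of GRCh38.p14, which was used for names, chromosome membership and gene order, with no coordinates printed. For each gene the probe set with the highest mean log2 signal was taken, and genes with a mean under 6.48, the median of all probe sets, were left out. XIST, TSIX and Y-linked genes were left out of every test. This left 11204 genes, 7413 of them with several probe sets. A probe set whose name ends in _s_at or _x_at can also detect related transcripts, which applies to MAN2B1, STMN1, HNRNPLL, LPL, TCL1A, CD38, FDX1, DLAT, IRF7, BANK1, CD72, CD79B, RPL22, RPLP1 and RPL12 among the genes named, so their values are uncertain to that extent. Of the genes named, FCRL2, BCL2, ATM and ATP6V0A2 had probe sets that disagreed in direction.

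Samples were grouped by the labels into stable (36) and progressive (32) disease. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate. The 25 gene lists and 9 cell type marker lists were fixed from textbook knowledge before the data were examined, as were the main test, the rule for named genes and most alternatives. Lists with at least 5 tested members were tested with camera, with fry, and with 100000 permutations of the labels on the list's mean level relative to all tested genes; that permutation was added after seeing the data. Fry tests whether a list's genes move, on balance, in 1 direction and does not compare the list with other genes. Cell type scores are the mean over tested markers of z-scored log2 values. Scores, components and quality measures were compared by two-sided permutation tests with 100000 resamples, exact where a group had fewer than 10 arrays. Relations across arrays were tested with 100000 permutations. The classifier was a diagonal linear discriminant on 100 genes, with 100 label permutations. Named genes are those passing the test, here none, then the 6 with the smallest p in each direction, 11 fixed CLL genes, and up to 4 members with the smallest p of each list that camera called. Of the fixed genes 1, and of the gene lists 2, are not reported here.

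The arrays were scanned on 7 days in 3 projects. Of the scan days 4 hold both groups and 3 hold 1 group, 10 arrays in all. Each of the 68 arrays had a chip lot entry of its own, so lot could not serve as a batch. Pairs of arrays sharing a leading title number had a median correlation of 0.956, against 0.886 for all other pairs. The median correlation of an array with the others was under 0.85 for 13 arrays, 7 stable and 6 progressive. Alternatives covered the pseudocount, the filter, normalization, the choice of probe set, the test, array weights, blocks for scan day, project and title number, quality and cell type covariates, single batches, and leaving out those 13 arrays.

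The code was tested on simulated data made from the residuals of the real arrays, with shuffled labels and 200 of 11204 genes changed. Over 10 draws limma recovered 1.65% of genes changed by 0.25 log2 units, 44.2% of those changed by 0.5 and 92.6% of those changed by 1, with a mean false share of 0%, 2.57% and 2.98%. With no gene changed it called 0. Camera with the preset correlation called a median of 4 and up to 6 of 25 lists in such data with no change, and with an estimated correlation it called 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.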

Results

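Gene expression was measured in leukemic lymphocytes from patients with chronic lymphocytic leukemia (CLL), a cancer of mature B cells, using Affymetrix HG-U133 Plus 2.0 arrays. The series holds 68 arrays, 36 from stable and 32 from progressive disease, and was made for a prognostic expression signature. The question was which genes, gene groups or cell types differed between progressive and stable disease. The array median signal ranged from 63.6 to 190, and the number of arrays sets the precision. Each difference is progressive minus stable on the log2(signal + 16) scale, which understates the change of dim genes. The labels do not say that every sample came from a separate patient, and 7 pairs of samples share the leading number of their title, 3 pairs in the stable group and 4 in the progressive group. The p-values therefore measure the spread between these arrays.

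No gene differed between progressive and stable disease after adjustment. Of 11204 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.419. At an unadjusted p under 0.05 there were 546 genes, 361 higher and 185 lower, against 560 given by chance. The exact rank-sum test also called 0 genes, with 520 at an unadjusted p under 0.05. The median standard error of a difference was 0.145, and the 95% interval lay within 1 log2 unit of 0 for 10852 genes (96.9%). Differences of a log2 unit or more were measured for 19 genes, the largest being 1.36 in size.

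The genes with the smallest p values are given although none passed. MAN2B1, a lysosomal mannosidase, had a mean of 11.1 ± 0.32 (SD, n = 36) in stable and 11.5 ± 0.44 (SD, n = 32) in progressive disease, a difference of 0.41 (SE 0.095, adjusted p = 0.419). RNFT2, which encodes a RING finger membrane protein, had a difference of 0.96 (SE 0.23), and TLCD4 of 1.14 (SE 0.28), both with adjusted p = 0.419. B4GALT2, a Golgi galactosyltransferase, had a difference of 0.49 (SE 0.12), FBRSL1 of 0.51 (SE 0.13) and ZNF787 of 0.45 (SE 0.12). In the other direction, STMN1, which destabilises microtubules, had a difference of -0.56 (SE 0.15), and HNRNPLL, a regulator of alternative splicing in lymphocytes, of -1.0 (SE 0.27). The noncoding RNA OLMALINC, close to the signal filter with means of 6.9 in stable and 6.2 in progressive disease, had a difference of -0.68 (SE 0.20). Its difference was -0.99 with a pseudocount of 1 and -0.40 with a pseudocount of 64. RDX, which links actin to the plasma membrane, had -0.45 (SE 0.13), the ubiquitin ligase gene PJA1 -0.36 (SE 0.11) and the circadian clock gene PER2 -0.37 (SE 0.11). Adjusted p among the 12 genes ran from 0.419 to 0.633. With scan day as a fixed block, limma called 1 gene, MAN2B1, with a difference of 0.52 (adjusted p = 0.00854).

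**Figure D1:**
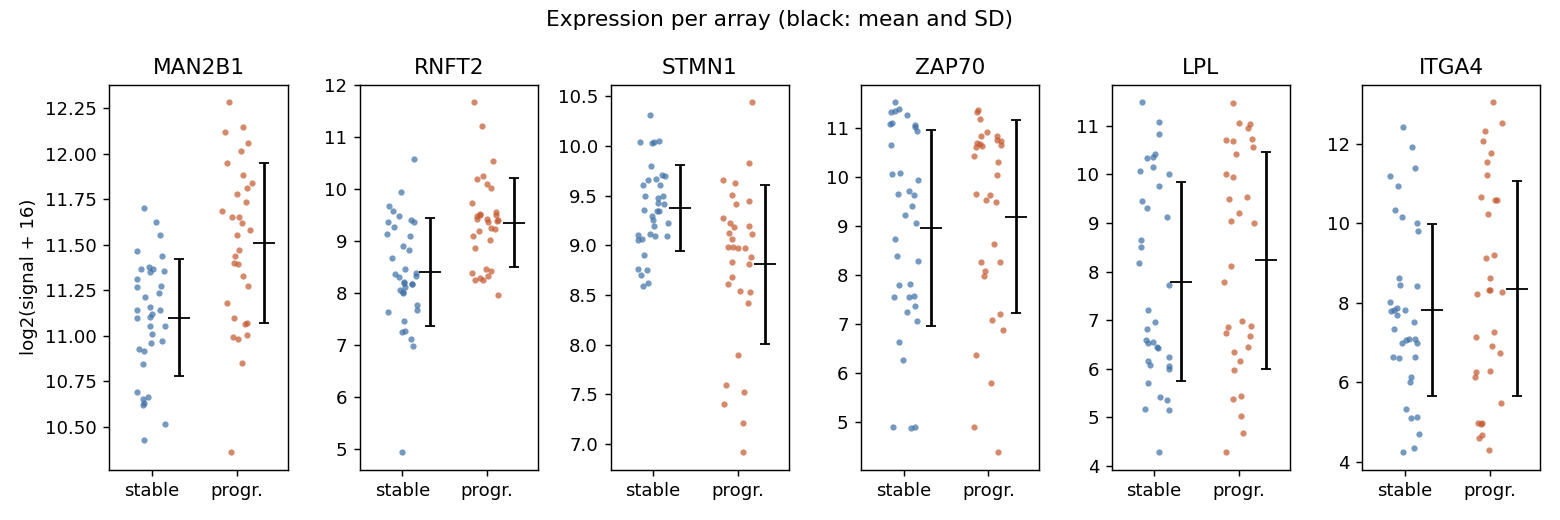
Expression of 6 genes on the log2(signal + 16) scale, 1 point per array, for 36 stable and 32 progressive samples, with the mean and SD in black and a separate vertical axis per gene. The groups overlap in every panel, and the adjusted p of MAN2B1 and RNFT2, the smallest, was 0.419.

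Genes used as prognostic markers in CLL did not differ between the groups. ZAP70, a kinase of T cell receptor signalling that is also made by part of CLL cases, had a difference of 0.24 (SE 0.47, 95% interval -0.70 to 1.18). LPL, lipoprotein lipase, had a difference of 0.44 (SE 0.51), and ITGA4, the integrin subunit CD49d, of 0.53 (SE 0.57). FCRL2, an Fc receptor-like protein, had 0.05 (SE 0.31), TCL1A 0.09 (SE 0.42), the antiapoptotic gene BCL2 -0.09 (SE 0.24) and the DNA damage kinase gene ATM -0.0069 (SE 0.16). These 7 genes had an adjusted p of 0.994 or 0.997. The wide intervals of ZAP70, LPL and ITGA4 go with SDs of 2.0 to 2.7 within the groups. Within 3 sets of arrays, called projects 1, 2 and 3 after a field of the array files, the difference was -1.45, 0.21 and 1.08 for ZAP70, -1.18, 0.16 and 1.20 for LPL, and -1.62, 1.67 and -0.13 for TCL1A, with limma adjusted p from 0.139 to 1. In a test of whether the difference itself differed between the projects, none of these 3 genes passed an adjusted p of 0.05. CD38 was too dim for the tested set and had a difference of -0.23 (SE 0.30) among all genes. CLLU1 and ADAM29 had no probe set of their own in the annotation table used here.

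Of 25 gene lists fixed beforehand, camera with its preset correlation of 0.01 called 4, and none was called with an estimated correlation, by fry or by permutation of the group labels. The list of chromosome 12, whose gain is recurrent in CLL, had the smallest p. Of its 609 tested genes 478 were higher in progressive disease, with a mean difference of 0.12 and a camera adjusted p = 1.03e-09. At an unadjusted p under 0.05 there were 55 of its genes, all higher, and 1 passed when adjusted over the list alone against 0 over all genes. Adjusted p = 0.282 with an estimated correlation, and the label permutation gave p = 0.00999 (adjusted p = 0.25). Its smallest p values were those of RNFT2, FBRSL1, ATP6V0A2, a subunit of the vacuolar proton pump with a difference of 0.52 (SE 0.15), and MUC8, with 0.71 (SE 0.21). MUC8 lay close to the signal filter in stable disease (mean 6.51), and its difference was 0.90 with a pseudocount of 1 and 0.47 with 64. The list's mean difference was 0.13 with scan day as a block. Within the 4 scan days that hold both groups it was -0.06, 0.16, 0.41 and 0.14, and within the projects -0.05, 0.25 and 0.11. The 0.41 is that of scan day 5, which holds 5 stable and 2 progressive arrays.

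The list of 11q22-q23, a region around ATM that is often lost in CLL, was called lower. Of its 20 tested genes 17 were lower, with a mean difference of -0.12 (camera adjusted p = 0.00237, adjusted p = 0.282 with an estimated correlation). Of them 1 passed when adjusted over the list alone, against 0 over all genes. RDX had the smallest p, followed by FDX1 with -0.20 (SE 0.11), NPAT with -0.15 (SE 0.098) and DLAT with -0.23 (SE 0.16). The mean was -0.13 with scan day as a block, and -0.18, 0.01, 0.02 and -0.22 within the 4 scan days. It was -0.20, 0.01 and -0.20 within the projects. Without the 13 arrays that correlate least with the others, its mean was -0.07 and camera no longer called it (adjusted p = 0.148).

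Cytosolic ribosomal proteins and interferon-stimulated genes were called higher. Of 38 ribosomal protein genes 35 were higher, with a mean of 0.07 (camera adjusted p = 0.00237). Adjusted p = 0.745 with an estimated correlation, which was 0.811 between these genes, and quantile normalization turned the mean to -0.01. With T cell, NK and monocyte scores as covariates its mean was 0.04 and camera no longer called it (adjusted p = 0.463). With the GAPDH and ACTB 3-prime over 5-prime ratios, signs of RNA quality, as covariates the ribosomal mean was 0.02 and the call was also lost (adjusted p = 0.348). Without the 13 arrays that correlate least with the others it was 0.11 (camera adjusted p = 9.56e-09, adjusted p = 0.65 with an estimated correlation). RPL22, RPLP1, RPL8 and RPL12 had differences of 0.14 (SE 0.094), 0.14 (SE 0.11), 0.11 (SE 0.082) and 0.11 (SE 0.089). Within scan days the ribosomal mean was 0.43, 0.05, 0.05 and -0.08, within projects 0.51, -0.22 and 0.05, and with scan day as a block 0.07. Of 24 interferon-stimulated genes 17 were higher, with a mean of 0.14 (camera adjusted p = 0.0303, adjusted p = 0.589 with an estimated correlation). The antiviral GTPase gene MX1 had a difference of 0.41 (SE 0.16), LY6E 0.45 (SE 0.20), the transcription factor gene IRF7 0.31 (SE 0.15) and the exonuclease gene ISG20 0.27 (SE 0.14). The interferon mean was 0.34, 0.01, 0.41 (scan day 5, with 2 progressive arrays) and 0.03 within scan days and 0.21, 0.28 and -0.0051 within projects. It was 0.13 with scan day as a block (camera adjusted p = 0.0609), 0.13 with no filter on dim genes (camera adjusted p = 0.162), and -0.02 without the 13 arrays (camera adjusted p = 0.79). No member of either list passed, over all genes or adjusted over the list alone.

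**Figure D2:**
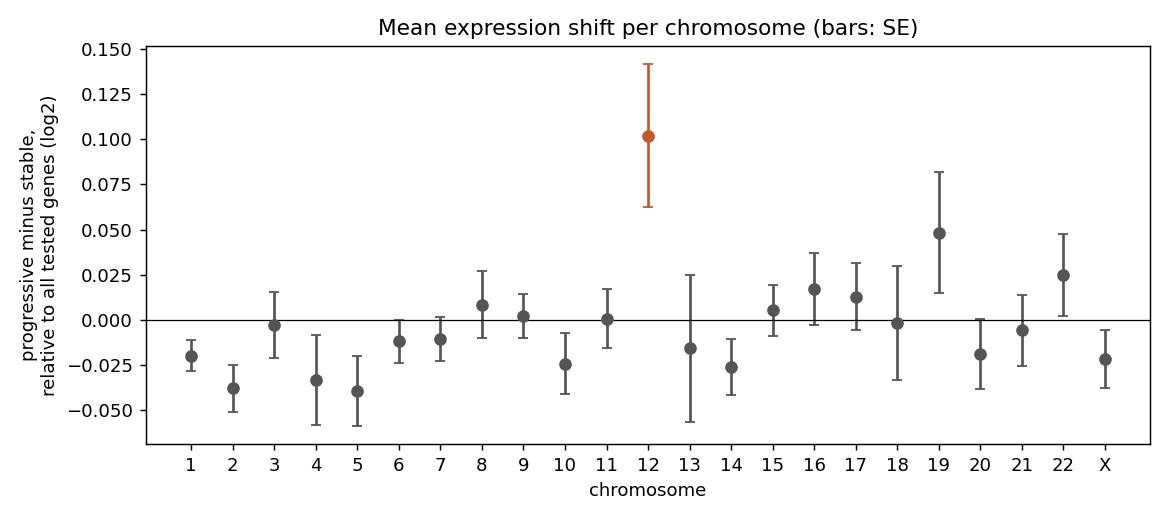
Mean progressive minus stable difference of the tested genes of each chromosome, relative to all tested genes, in log2 units with the SE over 36 stable and 32 progressive arrays as bars. Chromosome 12 has the largest shift, 0.10 with an SE of 0.040, and its label permutation p was 0.00999 (adjusted p = 0.115 over the 23 chromosomes drawn). The smallest label permutation p was that of chromosome 2, 0.0041, with a shift of -0.038 (SE 0.013, adjusted p = 0.0943).

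The other lists were not called. Among lists of CLL biology, 10 of 11 markers of unmutated or poor-outcome CLL were higher, with a mean of 0.39 (camera adjusted p = 0.0784), and without the 13 arrays that correlate least with the others camera called this list with a mean of 0.46 (adjusted p = 0.0453, adjusted p = 0.65 with an estimated correlation). Of 7 markers of mutated or favourable CLL 4 were higher, with a mean of -0.12 and a median of 0.05 (adjusted p = 0.70). B cell receptor signalling had 19 of 26 genes higher (adjusted p = 0.0688) and its early response genes 12 of 17 (adjusted p = 0.327). Of NF-kB targets 12 of 16 were lower (adjusted p = 0.455). For growth and death, 10 of 18 cell cycle genes were lower (adjusted p = 0.455) and 14 of 21 BCL2 family and apoptosis genes higher (adjusted p = 0.16). The list of 13q14 had 11 of 15 genes higher (adjusted p = 0.167). MYC targets had 13 of 24 genes higher (adjusted p = 0.619), oxidative phosphorylation 24 of 43 lower (adjusted p = 0.386), and glycolysis and hypoxia 12 of 21 higher (adjusted p = 0.806). Of MHC class II presentation genes 10 of 16 were higher (adjusted p = 0.806), of homing and adhesion genes 14 of 24 higher (adjusted p = 0.0677), and of WNT pathway and surface antigen genes 11 of 18 lower (adjusted p = 0.357). The Notch list had 6 of 11 genes higher (adjusted p = 0.806), with 1 gene passing when adjusted over the list alone. RNA splicing factors had 20 of 25 genes lower (adjusted p = 0.0738), the TGF-beta pathway 12 of 17 lower (adjusted p = 0.0688), and the unfolded protein response 13 of 19 lower (adjusted p = 0.187). Handling and storage response genes, which cells raise during processing, had 11 of 13 genes higher (adjusted p = 0.16). Camera called the handling list with scan day as a block (mean 0.40, adjusted p = 0.0436) and without the 13 arrays (mean 0.35, adjusted p = 0.0152), with adjusted p = 0.709 and 0.65 with an estimated correlation. Of the lists not called, 10 were called in at least 1 alternative setting, among them RNA splicing factors in 3 settings, homing and adhesion in 3 and the TGF-beta pathway in 2. With an estimated correlation none of these calls held, with adjusted p from 0.0957 to 0.709.

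Scores of cell type markers did not differ between the groups. The B cell score was -0.11 ± 0.65 (SD, n = 36) in stable and 0.12 ± 0.49 (SD, n = 32) in progressive disease, in z-score units (permutation test, two-sided, adjusted p = 0.49). Camera called the B cell list, with 9 of 10 genes higher and a mean of 0.22 (adjusted p = 0.0302, adjusted p = 0.431 with an estimated correlation). Its smallest p values were those of the signalling adaptor gene BANK1 with 0.60 (SE 0.32), MS4A1, which encodes CD20, with 0.32 (SE 0.18), CD72 with 0.49 (SE 0.31) and CD79B with 0.34 (SE 0.27), none of which passed. The list's mean was 0.13, 0.48, 1.22 and 0.03 within scan days, the 1.22 being that of day 5, with 2 progressive arrays. It was -0.04, 0.79 and -0.05 within projects, and 0.28 with scan day as a block. Without the 13 arrays that correlate least with the others the list's mean was 0.04 and camera no longer called it (adjusted p = 0.734), with differences of 0.25 for BANK1, 0.01 for MS4A1, 0.23 for CD72 and 0.02 for CD79B. Differences in score were -0.19 for T cells, -0.0056 for NK and cytotoxic cells, -0.12 for monocytes, 0.03 for neutrophils and -0.15 for platelets. They were 0.22 for erythroid cells, -0.0070 for plasma cells and 0.16 for dendritic cells, with adjusted p from 0.49 to 0.967. The T cell score rests on CD6, LCK and TRBC1, the 3 listed markers above the signal filter. Camera adjusted p was 0.851 for NK and cytotoxic cells, 0.294 for monocytes, 0.851 for plasma cells and 0.294 for dendritic cells; the plasma cell list had a mean of 0.0084 and a camera direction of lower.

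The largest variation between arrays did not follow disease course. Component 1 held 23.8% of the variance, component 2 held 8.53% and component 3 held 5.35%. Disease group accounted for 0.0981%, 0.352% and 4.31% of their scores (permutation test, adjusted p = 0.801, 0.801 and 0.271). Scan day accounted for 44.4% of component 2 (permutation p = 5e-04). Component 2 rose with the GAPDH 3-prime over 5-prime ratio, a sign of RNA degradation, with r = 0.771 (permutation p = 1e-05, the smallest the test can give, adjusted p = 3e-05 over 3 components) and rho = 0.617 (p = 1e-05). Without the 2 arrays farthest from the median ratio r was 0.654, and within the projects it was 0.922, 0.604 and 0.814. No quality measure differed between the groups over all arrays, with adjusted p from 0.658 to 0.935. The log2 GAPDH ratio was 0.40 ± 0.28 (SD, n = 36) in stable and 0.55 ± 0.63 (SD, n = 32) in progressive disease, and the log2 ACTB ratio 1.05 ± 0.60 and 1.30 ± 1.11. With group in the model, 2661 genes differed between scan days.

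**Figure D3:**
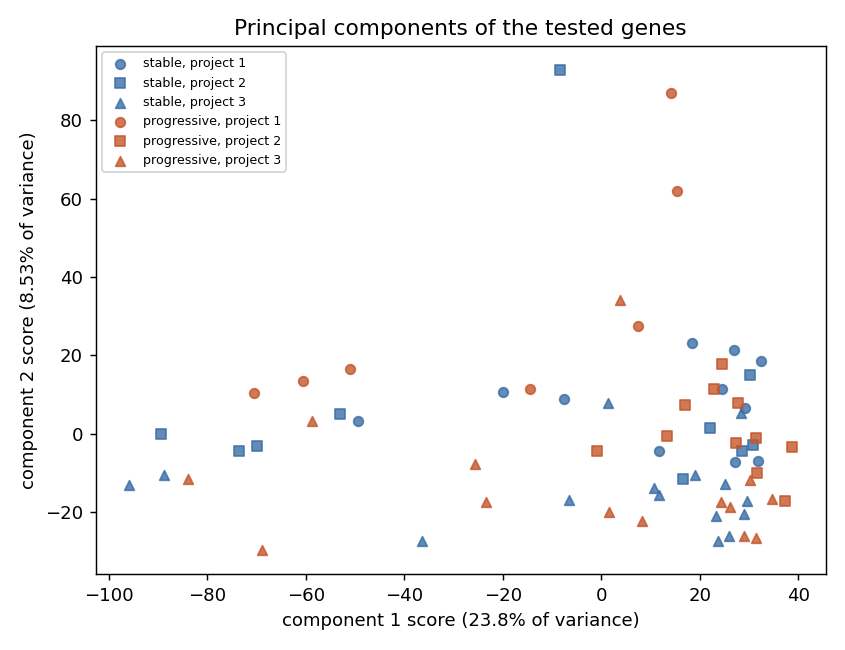
Scores of components 1 and 2 for 68 arrays, coloured by disease group, with a marker for each of 3 projects. The groups overlap on both axes, with disease group accounting for 0.0981% of component 1 and 0.352% of component 2.

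The array files name 3 projects, with 11 stable and 7 progressive arrays in project 1, 10 and 11 in project 2, and 15 and 14 in project 3. The difference between the disease groups was not alike in them. Limma called 363 genes within project 1, 130 higher and 233 lower, 1 gene within project 2 (CORO1B, named after its values were seen) and 0 within project 3. At an unadjusted p under 0.05 there were 2605 genes within project 1, 2665 within project 2 and 379 within project 3. In a test of the difference itself, 831 genes had a group by project interaction at an adjusted p under 0.05. The first of them by p, SGPL1, which breaks down sphingosine phosphate, had differences of -0.85 (SE 0.16), 0.41 (SE 0.15) and -0.18 (SE 0.14) in projects 1, 2 and 3. NNT, a mitochondrial transhydrogenase, had -1.29 (SE 0.32), 0.88 (SE 0.28) and -0.20 (SE 0.18). Both were named after their values were seen. Over all genes, the differences of projects 1 and 2 correlated at -0.483, those of projects 1 and 3 at 0.247 and those of projects 2 and 3 at -0.173; this is across genes, which are not independent replicates. In project 1 the log2 GAPDH ratio was 0.45 ± 0.23 (SD, n = 11) in stable and 1.21 ± 1.01 (SD, n = 7) in progressive disease (exact permutation test, p = 0.01, adjusted p = 0.0312 over 6 tests). Leaving out the progressive array with the highest ratio took the difference from 0.76 to 0.51 (exact permutation p = 0.0259). Leaving out the 2 highest took it to 0.18 (exact permutation p = 0.142), so the GAPDH difference rests largely on 2 arrays. The log2 ACTB ratio in project 1 was 0.79 ± 0.28 in stable and 2.02 ± 1.70 in progressive disease (SD, exact permutation p = 0.0104, adjusted p = 0.0312). No array was left out for that ratio. Of the 13 arrays that correlate least with the others, project 1 held 5 of its 7 progressive and 0 of its 11 stable arrays, and project 2 held 5 of its 10 stable and 0 of its 11 progressive arrays. Without them 4 interaction genes were called, against a median of 47.5 (0 to 2762) in 50 random removals of as many arrays from the same groups and projects.

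To ask whether the groups can be told apart by expression, each array was left out in turn and classified with 100 genes chosen on the other arrays. The area under the ROC curve was 0.651, and 42 of 68 arrays (61.8%, exact binomial 95% interval 49.2 to 73.3) were assigned to their group. Of 100 label permutations 1 gave an area as high (p = 0.0198). When whole scan days were left out together the area was 0.504 (p = 0.446), and when samples sharing a title number were left out together it was 0.583 (p = 0.099). Choosing the 100 genes once on all arrays gave an area of 0.935, while permuted labels treated in the same way had a median of 0.885.

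**Figure D4:**
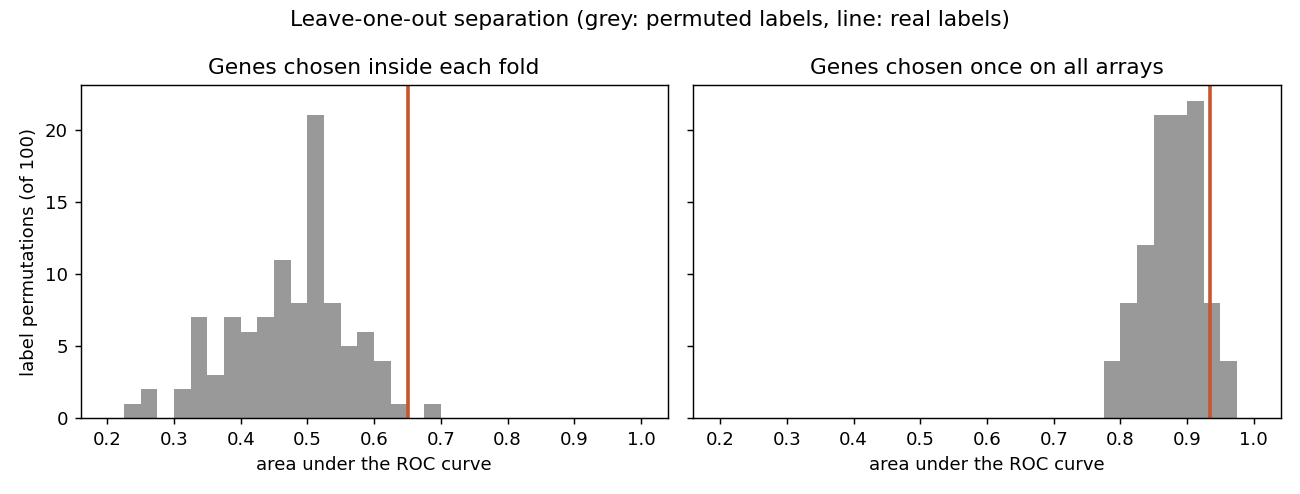
Area under the ROC curve in leave-one-out classification for 100 permutations of the labels (grey) and for the real labels (line), with genes chosen inside each fold (left) or once on all arrays (right). Real labels gave 0.651 against a permuted median of 0.49 on the left, and 0.935 against 0.885 on the right.

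ZAP70 was followed across arrays because T cells left after negative selection also make it. It rose with LPL, with r = 0.707 and rho = 0.738 over 68 arrays (permutation p = 1e-05 for each, the smallest the test can give, adjusted p = 2e-05 over 2 relations). The correlation was 0.663 within the stable and 0.752 within the progressive group, and 0.629, 0.649 and 0.792 within the projects. Without the 2 arrays farthest from the median of LPL it was 0.691. With the score of CD6, LCK and TRBC1, of which CLL cells also make CD6 and LCK, ZAP70 had r = 0.305 (permutation p = 0.0107, adjusted p = 0.0107) and rho = 0.229 (p = 0.0593). That correlation was 0.193 within the stable (p = 0.259) and 0.421 within the progressive group (p = 0.0159), 0.346, 0.312 and 0.376 within the projects (p = 0.163, 0.168 and 0.0431), and 0.286 (p = 0.0196) without the 2 arrays farthest from the median score. With a score of all 16 T cell markers on the array the relation was not seen, with r = -0.108 (permutation p = 0.38) and rho = -0.0287 (p = 0.815), -0.0722, -0.435 and 0.189 within the projects, and 0.0311 without the 2 farthest arrays. Of the 16 markers, 13 lie under the signal filter, so this score rests mostly on dim markers. A score of those 13 alone had r = -0.269 (permutation p = 0.0262), rho = -0.157 (p = 0.202), and r = -0.127 without the 2 farthest arrays.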

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

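Among the tests below, the shuffles within projects, the restriction to scan days that hold both groups, scan day in the model, 1 sample per title number, removal of arrays and the shuffled covariates were chosen after the result was seen; the test with RNA quality ratios and the splits of project 1 and of scan day 2 were set before theirs.

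The difference between progressive and stable disease itself differed between the projects, in a test of the interaction, for 831 genes. Of these, 583 were lower in progressive disease in project 1 and higher in project 2, and 234 went the opposite way. Chance is unlikely but not excluded: of 100 assignments of labels within projects, the real one included, 1 gave as many genes. The highest of the others gave 21. These assignments treated each array as separate, although arrays sharing a title number correlated at 0.412 in the model with title number as a block. The count of 363 genes within project 1 was likewise reached by 1 of 100 splits of its arrays, the real one. The highest other count was 1, with no allowance for the 3 projects tested. All arrays of scan day 2, 8 stable and 4 progressive, belong to project 1, so its count is not separate from that of project 1. Within scan day 2 the real split gave 419 genes, and 2 of 100 splits gave as many. That is a share under 0.05 with no allowance for the 3 single days tested, of which days 4 and 7 gave 0 genes. The highest other count, 484, is above the real one and came from a split that shares 3 of its 4 progressive arrays with it. With 1 sample per title number 1497 genes had the interaction.

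Scan days that hold 1 group are not needed for the interaction. With only the 4 scan days that hold both groups (58 arrays) 844 genes had it. The highest count in 99 shuffles of their labels within projects was 163. These shuffles did not keep the unequal shares of the groups on the days of project 2. Day 4 holds 5 stable and 9 progressive arrays, and day 5 holds 5 and 2, so an effect of scan day in general was not tested in this way. Unequal RNA quality and a minority of arrays stay open. These candidates overlap: the 2 progressive arrays of project 1 with the highest GAPDH ratios are among the 13 least correlated arrays. With the GAPDH and ACTB 3-prime over 5-prime ratios as covariates 0 interaction genes were left, the outcome set beforehand for RNA quality as the cause. Yet the same ratios shuffled within group and project left under 50% of the count in 52 of 99 draws. With the real ratios a gene kept a median of 81% of its project 2 minus project 1 effect (median size 1.10 against 1.38, median SE 0.358 and 0.361). The effect of project 3 was not measured in this way. The loss of calls therefore does not decide. Scan day in the model left 71 genes, which does not decide either, since shuffled scan days gave under 50% of the count in 69 of 99 draws. Without the 13 arrays that correlate least with the others 4 genes were left. However, 50 random removals of as many arrays from the same groups and projects gave 0 to 2762, with a median of 47.5. The count of 831 thus depends strongly on which arrays are kept. Whether the 13 arrays account for the interaction therefore cannot be told apart, although they lie in opposite groups in projects 1 and 2 (5 of 7 progressive and 0 of 11 stable, against 0 of 11 and 5 of 10). A difference between the patients of the projects is a further candidate explanation and was not tested. Some pairs of samples sharing a title number lie in different projects, so the projects may hold some of the same patients.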

How the results depend on the processing

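Settings chosen after seeing the data are the project as a block, single projects, removal of the 13 arrays that correlate least with the others, label permutation of lists, an estimated correlation in the other settings, quality ratios as covariates of lists, the GAPDH ratio without its highest arrays, all markers on the array, and genes chosen once on all arrays. Apart from the splits of project 1 and of scan day 2 and the permuted labels for genes chosen once, the cause of the changes below was not tested. The count of 0 changed genes stayed at 0 in all settings but these: 1 with scan day as a fixed block, 419 within scan day 2, which is part of project 1, 363 within project 1 and 1 within project 2 (CORO1B). The smallest adjusted p of the settings ran from 0.0032 to 1. Depth is limited by signal over background, since genes under the median signal were left out; without that filter the count stayed at 0 of 19740. The 4 lists called became 0 with an estimated correlation, 0 by fry, 0 by label permutation, 7 with scan day as a block (3 of the 4 among them), 7 with 1 sample per title number (all 4 among them) and 8 with T cell, NK and monocyte scores as covariates (3 of the 4 among them). Without the 13 arrays 6 were called, only 2 of the 4 (ribosomal proteins and chromosome 12) among them. The separation of the groups, 0.651, lost its call with 25 genes (0.629), 500 genes (0.566), shared title numbers left out together (0.583), scan days left out together (0.504), genes chosen once (0.935, against permuted labels) and without the 13 arrays (0.619, on 55 arrays), and held with quantile normalization (0.632). Cell type scores, components and quality measures kept their side of the threshold in every setting run outside single projects. Within project 1 the GAPDH and ACTB ratios passed (exact permutation test, adjusted p = 0.0312 for each). By r, both ZAP70 relations kept theirs with quantile normalization and without the 2 farthest arrays. By r, the relation with the T cell score did not pass with all markers on the array, within the stable group or within projects 1 and 2. Its rho did not pass over all arrays (0.229, permutation p = 0.0593) or without the 2 farthest (0.195, p = 0.117).

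Single values that turned sign, none past the threshold, follow. With the mean of all probe sets BCL2 was 0.0056 and ATM 0.0064; with array weights FCRL2 was -0.12; with scan day as a block ZAP70 was -0.18 and ATM 0.0076. With shared title numbers as a random block ATM was 0.019. With 1 sample per title number ATM was 0.015, the score of NK and cytotoxic cells 0.026, of platelets 0.050, of plasma cells 0.059, and the trimmed mean differed by -6.82e-05. With quality ratios as covariates FCRL2 was -0.053 and ATM 0.027, and with cell scores as covariates BCL2 was 0.13 and ATM 0.11. Quantile normalization gave -0.0103 for the ribosomal list and -0.0345 for the neutrophil score. Without the 13 arrays FCRL2 was -0.21 and the interferon list -0.016. With all markers on the array the scores were 0.041 for T cells, -0.060 for neutrophils, 0.12 for platelets and 0.038 for plasma cells.

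Within scan day 2 TLCD4 was -0.52, ZAP70 -2.73, LPL -1.09, FCRL2 -0.024, TCL1A -2.46 and CD79B -0.25. Within scan day 4 RDX was 0.055, ZAP70 -1.04, LPL -0.68, BCL2 0.42, ATM 0.27, FDX1 0.21 and DLAT 0.22. Within scan day 7 FCRL2 was -0.34, RPL22 -0.011, RPLP1 -0.030, RPL8 -0.051, RPL12 -0.075 and MS4A1 -0.13. Within project 1 TLCD4 was -0.16, ZAP70 -1.45, LPL -1.18, TCL1A -1.62 and CD79B -0.37. Within project 2 BCL2 was 0.68, ATM 0.85, DLAT 0.43, RPL22 -0.13, RPLP1 -0.21, RPL8 -0.022 and RPL12 -0.095. Within project 3 ITGA4 was -0.22, FCRL2 -0.39, TCL1A -0.13, ISG20 -0.063, CD72 -0.15 and CD79B -0.089. Of the other values of single genes, lists and scores, 859 kept direction and side of the threshold, 10 gained a call and 16 lost one. Chip lot as a block was not run, since no lot held over 1 array, and scan day 5, with 2 progressive arrays, fell under the 3 per group set beforehand for a test of single days. In the rank-sum test 55 genes held tied values. No paired analysis was possible because the replicate numbers were given in order and no title number spans both groups.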

Other observations

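Of the tests below, those on chromosome 12 with scan day and RNA quality, the splits for the count of genes and of lists, the permuted labels for genes chosen on all arrays, and the relations with component 1 were chosen after a result was seen; the test by 4 parts of the chromosome was set before.

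The relative levels of many gene lists varied together across arrays of both groups, along the largest axis of variation. Of 30 lists 18 were related to component 1 at an adjusted p under 0.05. Each list's level was taken relative to all tested genes, whose mean can itself follow component 1, and no random lists were run. The count of 18 therefore does not show that these lists relate to it more than other genes do. Component 1 also sets apart most of the 13 arrays that correlate least with the others, with a median score of -69.9 against 23.8 for the other 55 arrays; 10 of them were among the 13 lowest scores. RNA splicing factors had the largest r, -0.86 (rho = -0.666), and r was -0.777 for the TGF-beta pathway, -0.694 for NF-kB targets, -0.69 for the unfolded protein response and 0.706 for B cell markers (rho = -0.558, -0.604, -0.518 and 0.476). The permutation p of these r and rho was 1e-05, except 4e-05 for rho of the B cell markers, and the adjusted p of each r was 2e-05. Without the 2 farthest arrays these r were -0.826, -0.783, -0.73, -0.725 and 0.649. Without the 13 arrays r was -0.788, -0.579, -0.535, -0.552 and 0.453 (rho = -0.557, -0.366, -0.393, -0.333 and 0.22), and 17 of 30 lists passed. Within projects 1, 2 and 3 they were -0.739, -0.882 and -0.9 for splicing factors, -0.726, -0.814 and -0.846 for the TGF-beta pathway, and -0.77, -0.716 and -0.743 for NF-kB targets. For the unfolded protein response they were -0.705, -0.702 and -0.75, and for B cell markers 0.365, 0.845 and 0.731. Single members related less to component 1 of all tested genes. Their median r was -0.384 for splicing factors, -0.141 for the TGF-beta pathway and -0.482 for NF-kB targets. It was -0.304 for the unfolded protein response and 0.32 for B cell markers. The mean level of 13 handling and storage response genes, relative to all tested genes, fell as component 1 rose, with r = -0.769 and rho = -0.774 (permutation p = 1e-05 for each, the smallest the test can give, adjusted p = 2e-05 over 30 lists). Component 1 was computed without the genes of the list. The correlation was -0.765 within stable and -0.821 within progressive disease, -0.832, -0.713 and -0.79 within the projects, -0.75 without the 2 farthest arrays and -0.772 without the 13. For 17 B cell receptor early response genes r was -0.796 and rho -0.799, and r was -0.801 within stable and -0.833 within progressive disease, -0.829, -0.768 and -0.82 within the projects -0.786 without the 2 farthest arrays and -0.734 without the 13; NR4A1 is on both lists. B cell receptor signalling genes went the other way, with r = 0.679 and rho = 0.476 (permutation p = 1e-05 and 6e-05). Their r was 0.835 within stable and 0.449 within progressive disease, and 0.518, 0.75 and 0.73 within the projects. It was 0.62 without the 2 farthest arrays and 0.375 without the 13 (rho = 0.206). CD79A, CD79B, CD22, BLK, BANK1 and CD72 are also among the B cell markers. As fixed, the unfolded protein response and handling lists share ATF3, HSPA1A, HSPA1B and DNAJB1. Relations of lists that share genes are not separate results. The mean progressive minus stable difference of the handling list was 1.35 in project 1, -0.42 in project 2 and 0.14 in project 3, and that of the early response list 1.11, -0.66 and 0.11.

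Genes with a group by project interaction were 7.42% of all tested genes, 6 of 16 MHC class II presentation genes and 9 of 38 ribosomal protein genes (Fisher's exact test across genes, which are not independent and correlate at 0.811 within the ribosomal list and 0.193 within the other, so that its p is too small, adjusted p = 0.0172 and 0.0186 over 25 lists). The mean difference of the ribosomal list was 0.51, -0.22 and 0.05 in projects 1, 2 and 3, and that of the MHC class II list -0.25, 0.35 and -0.01.

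Genes of chromosome 12 were higher on balance in progressive disease, by 0.10 relative to all tested genes (SE 0.0385 in a linear model), the largest shift of 23 chromosomes, and their correlation within groups, 0.0639, was also the highest. With scan day and the RNA quality ratios in the model the shift was 0.129 (SE 0.042), which argues against those as its whole source. A candidate explanation is more copies of the chromosome in part of the progressive samples; it predicts a shift along the whole chromosome, and the 4 parts of about equal gene number, in gene order, had 0.0975, 0.0913, 0.0692 and 0.15 (SE 0.047, 0.037, 0.048 and 0.041). The shift was 0.032, 0.148 and 0.0987 within the projects (SE 0.044, 0.069 and 0.067). Chance stays open, since the label permutation had an adjusted p = 0.25 over 25 lists, and no copy number was measured. Over the 23 chromosomes the label permutation of chromosome 12 had an adjusted p = 0.115. Chromosome 2 had a smaller p, 0.0041 (adjusted p = 0.0943), with a shift of -0.038 (SE 0.013).

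The relative level of the 11q22-q23 list differed by -0.14 (SE 0.065), and by -0.13 (SE 0.072) with scan day and the RNA quality ratios in the model, but by -0.08 (SE 0.063) without the 13 arrays that correlate least with the others.

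Chance cannot be excluded for the number of lists that camera called with its preset correlation: 4 were called with the real labels, 62 of 100 splits gave as many, and the highest other gave 13. For the count of 0 genes the splits say nothing about chance, since any split gives at least 0 (100 of 100, highest other 0).

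Gene choice on all arrays may account for most of the apparent separation of 0.935: with permuted labels the same procedure gave a median area of 0.885, against 0.49 when genes were chosen inside each fold.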
